A study of Mus musculus with 95 samples.

How the data were processed

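The data are probe counts from a GeoMx Digital Spatial Profiler experiment with the v1.0 mouse whole transcriptome atlas panel, per the labels. FFPE thymus of 4 mice with a mutant Gtf2i knock-in and of 4 control mice lay on 4 slides, and 95 segments were collected under masks for pan-cytokeratin, CD3 or B220, per the labels. Each label gives the mouse, cell class, genotype, slide, number of nuclei and area of its segment. The 8 groups were the classes the labels name: cortical and medullary epithelium and T cells and B cells in control, and epithelium, T cells and B cells in thymoma. Mice 1042, 1044, 1082 and 1157 carried thymoma. Controls 1057 and 1059 were Gtf2ifl/fl, and controls 1172 and 1143 Gtf2ifl/wt without Cre. Each slide held 2 mice of 1 genotype, so slide and control genotype lie within group. The file headers name 1 plate.

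The authors deposited whole-number counts per probe, 1 file per segment, made with GeoMx_NGS_Pipeline 2.0.0 and written in DCC format 0.02, per the file headers. The headers also give raw, trimmed, stitched and aligned reads. Totals of the deposited counts lie below the aligned reads, as they would after reads were collapsed by molecular identifier, which the headers do not put in words. Probes without a count are not listed in the deposited count files and were set to 0. The deposited counts carry no normalization or background correction. How reads were aligned to probes beyond the name of the pipeline is not given in the sources used here, and no genome build applies. For part of the deposited files the column holding the counts has no usable name, and these were read in the same way and checked to hold whole numbers. Sequencing saturation was computed as the percentage of aligned reads beyond the count total.

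Probe IDs could not be turned into gene names, because no table used here pairs them. The gene lists fixed in advance (cell types, pathways, the Gtf2i family) were therefore not used, and the targeted gene could not be looked at. As fixed for that case, probe sets called between control segment classes took their place, and only the 2 largest and 2 smallest fold changes of thymoma against cortical epithelium are named, from probes with an adjusted p below 0.05, a mean log2 level in the edgeR fit above the median and full separation of the 8 mice (408 probes). Negative control probes could not be told from the others, so no background was subtracted, and the stricter filter kept the upper part of probes by plain mean CPM over libraries, split at the median of that mean.

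The mouse was the replicate. Raw counts were summed over the segments of each mouse and class. Probes were kept by filterByExpr, libraries were scaled by TMM, and groups were compared with the edgeR (4.0.16) quasi-likelihood test in R 4.3.3, with a Benjamini-Hochberg adjusted p below 0.05 as the threshold. Only the groups compared entered a fit. Comparisons of classes within mice used the mouse as a block, since the labels give both classes of a mouse. Libraries of the same mouse deviated together from their class means, with correlations of 0.357 to 0.813 over probes, in each case above those with other mice. The margin was narrow for mouse 1172 in medullary against cortical epithelium, at 0.357 against 0.342. The interaction of group and compartment was tested in 1 fit with mouse as a block.

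Sets were, with the exception named below, the probes called between control segment classes: medullary and cortical (medulla against cortex), epithelial and T cell (epithelium against T cell segments), and B cell (B against medullary T cell segments, 439 higher in the former). In each comparison, sets came from libraries that were not compared, though from the same control mice. Epithelium and T cell segments also shared regions. Part of the movement of cortical and medullary sets thus follows from how they were called. For B cells, 2 more sets were called between epithelium and T cell segments of thymoma, so from the same thymoma mice. They were tested with limma (3.58.1) camera at a preset correlation, with camera at an estimated correlation and with fry, which asks whether a set moves on balance and does not compare it with other probes; 28 sets over the 5 comparisons formed 1 family. Set medians were set against 1000 random lists matched on mean level over all segments in 20 bins. Ranges over single thymoma mice compare log2 CPM with an unweighted mean over control libraries, in which shallow mouse 1143 weighs like the others. They are not on the scale of the edgeR medians. The position scale projects log2 CPM (prior count 2) of each mouse on the probes called between control cortex and medulla. Control mice were scored on an axis built without them. The spread of the epithelium against T cell contrast is the SD over probes of the log2 difference within a mouse. These single values were compared by exact two-sided permutation of mice, which exchanged mice singly and ignored the pairs on a slide. For the position, control mice with medulla were scored on other axes than the thymoma mice. Its values are thus not strictly exchangeable, and its p-values are nominal.

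Choices of test, sets and alternatives were made before the data were examined, other than those named next. The comparison of epithelium with T cell segments in control medulla was not among the comparisons fixed in advance. It gave the sets of 523 epithelial and 228 T cell probes. Added after the data were seen were the B cell sets and the sets from thymoma segments, the comparison of B cell with T cell segments, the overlaps between lists, the measures of depth and mask, quantile normalization, the counts without mouse 1143 beyond the planned leaving out of each mouse, thinning of libraries to a common total (103978 with all mice, 1490526 without mouse 1143), level-matched lists, set medians under other scalings and control genotypes, and a position whose axis and scale come from different control mice. Other settings, fixed beforehand, were RLE and upper-quartile normalization, no low-count filter, the stricter filter, the DESeq2 (1.42.0) Wald test, limma on mean log2 values per mouse, limma-voom on segments with mouse as a random block, leaving out segments under 200 nuclei or under 50% saturation (3 and 0 segments), only control mice of 1 genotype, leaving out each mouse, and for the position other axes and prior counts.

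Scripts were tested on simulated data drawn from the real means and library sizes with 200 probes changed. In thymoma against cortical epithelium, 29.9%, 91% and 100% of changes of 1.5-, 2- and 4-fold were recovered among 20175 probes, with 17 false calls. In thymoma against cortical T cells these shares were 25.4%, 70.1% and 95.5%, with 13 false calls. Simulated probes were drawn independently, and every mouse had the same mean profile apart from the changes. Shares in the real fits may therefore be lower. On the position scale, simulated thymoma epithelium placed at 0, 0.3 and 1 scored 0.365, 0.557 and 0.967 with all mice, so the scale reads too high near 0. With axis and scale from different mice these were recovered as 0.277, 0.504 and 1.011 with all mice, still too high near 0, and as −0.007, 0.299 and 1.015 without mouse 1143. No 2 segments of a group had identical counts.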

Results

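The series profiled thymus of 4 knock-in mice that carry a mutant Gtf2i, a gene for a general transcription factor, and develop thymoma, and of 4 control mice. The thymoma mice carried 1 floxed Gtf2i allele and Cre placed in Foxn1, the master regulator gene of thymic epithelium. RNA was measured in fixed, embedded tissue with a whole-transcriptome set of 20175 probe IDs, each probe counted in 95 small segments of tissue. Segments were chosen by a fluorescent marker: pan-cytokeratin for epithelium, CD3 for T cells and B220 for B cells. In control thymus they were also divided into cortex, where immature T cells are selected, and medulla, where T cells mature. The control segments comprised 13 of cortical epithelium and 13 of cortical T cells from 4 mice, 11 of medullary epithelium and 11 of medullary T cells from 3 mice, and 10 of B cells from 4 mice. The thymoma segments comprised 13 of epithelium, 12 of T cells and 12 of B cells, each from 4 mice. Mouse 1059 had no medullary segments.

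Segment totals ran from 8919 to 12551297 counts, with 130 to 8344 nuclei under each mask and a sequencing saturation between 67.6% and 90.1%. After summing the segments of each mouse and class, the libraries held 63805 to 36879809 counts. Control mouse 1143 stood apart, with 45.4 to 77.4 counts per nucleus against 544 to 3160 in the other 7 mice, and without it the smallest library held 413591 counts. Its slide mate, mouse 1172, was at 544 to 998. A floor of 3 counts corresponds to 0.0047% of the smallest library and to 8.13e-06% of the largest, which covers counting error only. The mice lay in pairs on 4 slides, each slide with 1 group and 1 genotype. No fit can therefore separate slide from group, or control genotype from control slide. No file or reference table used here paired the probe IDs with gene names. The results below therefore concern sets of probes defined by the control segments, and 4 probes by their IDs.

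**Figure D1:**
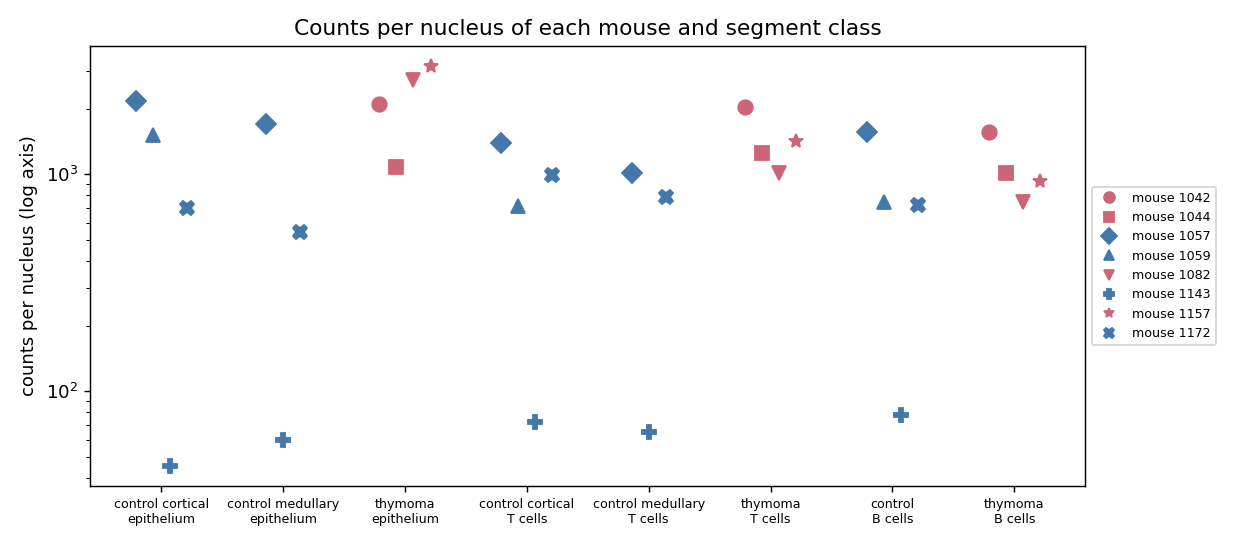
Counts per nucleus (log axis) of each summed library, by segment class and mouse, control mice in blue and thymoma mice in red. Mouse 1143 lies between 45.4 and 77.4 in each of its 5 classes, below the other mice, which lie between 544 and 3160.

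The normal tissue was compared first, to define what marks cortex and medulla. In epithelium segments of the 3 mice with both zones, 960 probes were higher in medulla and 1147 lower, with a median absolute change of 0.58 (log2) among the called. In T cell segments of the same mice, 952 were higher in medulla and 1039 lower. Both segment types shared part of this contrast: 465 probes were higher in medulla in both, where independent lists of these sizes would share 45.3, and 758 were lower in both, where 59.1 would be shared. The same mice and regions gave both lists, from different libraries, so the value for independent lists is not what chance would give. Each fit (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05) kept the mouse as a block, and without the block the counts were 0 in epithelium and 1 in T cells. The epithelium count was 668 without mouse 1057 and 1164 without mouse 1172, and the T cell count 867 and 547.

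Epithelium segments were then compared with T cell segments, to see what each mask captured. In control cortex, 596 probes were higher in epithelium segments and 21 in T cell segments, and in thymoma 2865 and 2227. Depth differed: control cortical epithelium libraries held 103978 to 8526921 counts, and those of thymoma 5262278 to 13328944. The median absolute change (log2) among the called was 0.398 in control cortex and 0.273 in thymoma. The counts thus do not rank how well the masks separate. Of the 596 epithelial probes of the control cortex, 544 were also higher in epithelium segments of thymoma, a group with no mouse in common, where independent lists would share 84.6. Across all probes, which are not independent replicates, the fold changes of both contrasts correlated with r = 0.62. Probes of the genes behind the gating markers may belong to these lists and would be no finding. Without gene names this could not be checked. The control count of 617 fell to 220 without mouse 1057, and without the block on mouse the counts were 0 in control cortex and 13 in thymoma. In thymoma the balance turned with the scaling, to 2430 higher and 3859 lower under upper-quartile normalization and 2657 and 3118 under quantile normalization.

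Thymoma epithelium was set against the cortical epithelium of control mice to ask how the mutant epithelium departs from its normal cortical counterpart. Of 20175 probes, 484 were higher in thymoma and 207 lower. The rises were the larger changes: 235 of them, and 5 of the falls, exceeded 1 log2 unit. Probes that marked epithelium segments in control medulla, a set not fixed in advance, numbered 523. Of these, 164 rose and 1 fell, with a median log2 fold change of 0.55. Each of the 4 thymoma mice lay above the control mean, by 0.41 to 0.77, where that mean weighs each control library alike, unlike the edgeR median. Among 439 probes that marked B cell segments, a set added after the data were seen, 46 rose and none fell. Their median was 0.42, and the thymoma mice lay 0.24 to 0.74 above the control mean. These counts depended on single mice of both groups. Without thymoma mouse 1042, 145 probes in all were called higher, and without control mouse 1172, 41. Without mouse 1143, 234 epithelial probes rose and 4 fell, and 114 B cell probes rose and none fell. Against the Gtf2ifl/fl controls 75 and 9 rose and 2 and 0 fell, and against the Gtf2ifl/wt controls edgeR called none of either set.

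Other normal sets had smaller medians in this comparison. Of 952 medullary probes, taken from T cell segments, 92 rose and 4 fell, with a median of 0.23. Of 1039 cortical probes, 18 rose and 3 fell, with a median of 0.17. Without mouse 1143 these numbers were 177 and 14, and 75 and 12, and against the Gtf2ifl/wt controls none was called. Of 228 probes that marked T cell segments, none rose and 2 fell, and their median of −0.09 lay 0.27 below lists of probes of the same mean level (set less matched lists −0.27). The same difference was 0.54 for the epithelial set, 0.30 for the B cell set, 0.22 for the medullary set and 0.04 for the cortical set, whose sign turned to −0.03 under quantile normalization and −0.05 against the Gtf2ifl/fl control mice. The epithelial set passed a camera test with a preset correlation (adjusted p = 9.24e-37), which was lost with an estimated correlation (adjusted p = 0.123), and the fry test of limma gave an adjusted p of 0.0139. For the B cell set these values were 4.99e-21, 0.232 and 0.044, and for the medullary set 1.5e-10, 0.234 and 0.0592. Without mouse 1143 the fry value was 0.0367 for the epithelial set, and for the B cell set it was lost (0.0905).

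Of the 691 called probes, 531 separated all 4 thymoma mice from all 4 control mice. Over all probes 14.7% did so, where chance gives 2.86%. Probe RTS0081628 was at 1000 ± 930 CPM (SD, n = 4) in thymoma epithelium and 64.5 ± 45.6 (n = 4) in cortical epithelium, a log2 fold change of 4.18 (SE 0.675, adjusted p = 0.00566). Probe RTS0081028 was at 47.9 ± 14.9 against 11.0 ± 11.3, with a log2 fold change of 3.07 in the edgeR fit (SE 0.309, adjusted p = 0.000237). The ratio of its 2 CPM means is smaller: they weigh each library alike, and the fit does not. In mouse 1143 a floor of 3 counts was 0.00289% of the cortical epithelium library. Probe RTS0067343 was at 57.8 ± 10.5 against 130 ± 27.1, a log2 fold change of −1.14 (SE 0.212, adjusted p = 0.0119). Probe RTS0067791 was at 73.1 ± 12.6 against 169 ± 52.2, a log2 fold change of −1.21 (SE 0.256, adjusted p = 0.0231). No probe of the 4 passed with limma on mean log2 values per mouse, or when only the Gtf2ifl/wt controls were kept, with log2 fold changes of 3.98, 2.33, −1.34 and −1.44 in the latter. Probe RTS0081628 also lost its call without mouse 1172 (adjusted p = 0.0667), and without mouse 1082 its log2 fold change fell to 3.29. Both falling probes lost theirs without mouse 1042, 1057, 1157 or 1172, with adjusted p of 0.0508 to 0.0883 for RTS0067343 and 0.0789 to 0.14 for RTS0067791. The latter also lost it against the Gtf2ifl/fl controls (0.0613) and under quantile normalization (0.0602). All 4 probes moved the same way in other classes. Against control cortical T cells their log2 fold changes, in the order above, were 3.55, 2.49, −1.01 and −1.18, none called with all mice. Between B cells they were 3.33, 2.01, −1.03 and −0.89, with only RTS0081028 called. These changes were thus not particular to epithelium.

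The count of 691 depended on single mice. It was 50 without mouse 1172, 63 without 1057, 110 without 1059, 157 without 1042, 195 without 1157, 1343 without 1082 and 1910 without 1143 (1192 higher and 718 lower). Against the Gtf2ifl/wt control mice alone it was 1. Upper-quartile scaling turned the balance to 407 higher and 818 lower, and it shifted the median of all probes to −0.18, from −0.04.

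**Figure D2:**
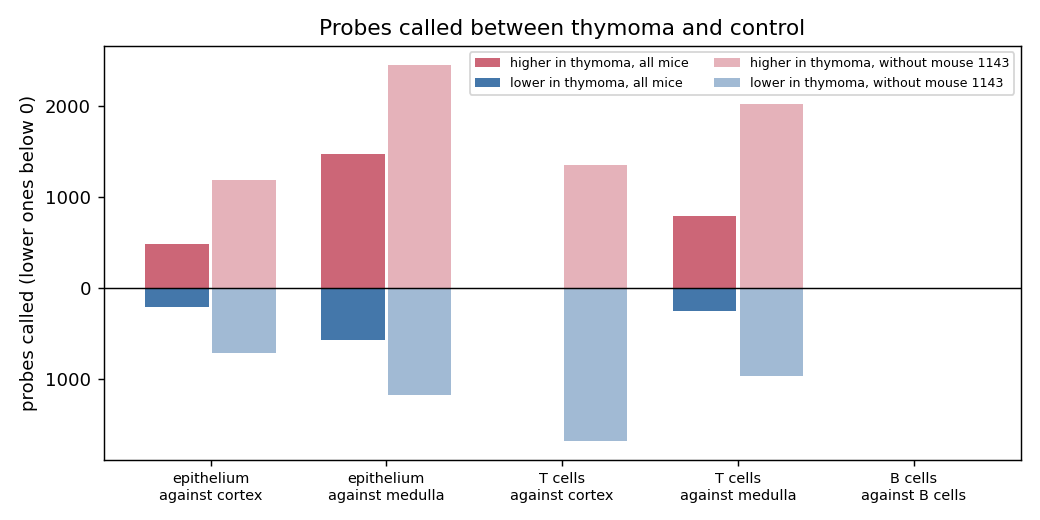
Number of probes called higher (above 0) and lower (below 0) in thymoma, for each comparison, with all mice (full colour) and without control mouse 1143 (pale). T cells against cortex go from 1 called probe to 3034 when that mouse is left out, and B cells stay at 1.

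Against medullary epithelium of control mice, probes that marked the cortex in control T cell segments were higher under the epithelial mask of thymoma. Of these 1039 cortical probes, 574 rose and none fell, with a median log2 fold change of 0.87. The 4 thymoma mice lay 0.78 to 1.07 above the unweighted mean of the medulla, a scale other than that of the edgeR median. The set had a camera adjusted p of 7.9e-70, which was lost with an estimated correlation (adjusted p = 0.123), and a fry adjusted p of 0.0084. T cells under the mask would carry such probes too. Against mouse 1057, the only Gtf2ifl/fl control with medulla, the set median was 0.735, 0.532 above level-matched lists. The count of risen probes depended on single mice. Without mouse 1172 only 5 probes in all were called higher, without 1157 109 and without 1042 212. Of 952 medullary probes, 127 fell and 16 rose, with a median of −0.13, and the mice lay between −0.26 and −0.03. Of 596 probes that marked epithelium in the control cortex, 217 rose and 4 fell, with a median of 0.78. Of 439 B cell segment probes, 99 rose and 7 fell, with a median of 0.53. All of these came from other libraries than those compared, but from the same control mice. Medullary T cell and epithelium segments also shared regions. The cortical set was called for being low there and the medullary set for being high. Part of their movement against medulla thus follows from how they were chosen.

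The comparison with medulla called 1469 probes higher and 567 lower. Set less matched lists was 0.64 for the cortical set, 0.57 for the epithelial set, 0.20 for the B cell set and −0.15 for the medullary set. The medullary value was −0.042 against the Gtf2ifl/wt controls, where 35 probes rose and 76 fell, and −0.289 against mouse 1057. Against that mouse the B cell value was 0.084, and the epithelial value 0.364. The medullary set had a camera adjusted p of 0.00307, an adjusted p of 0.622 with an estimated correlation and a fry adjusted p of 0.241. Upper-quartile scaling gave 1170 higher and 3789 lower with a median of −0.31 over all probes, and quantile normalization gave 942 and 621. The count of 2036 was 30 without mouse 1172, 158 without 1157, 291 without 1042, 805 without 1082, 1035 without 1044 and 3627 without 1143.

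Each mouse was also given a single position between both zones. On a scale where control cortex is 0 and control medulla 1, built from the probes called between both zones, thymoma epithelium scored 0.367 ± 0.083 (SD, n = 4). Control cortical epithelium, each mouse scored on an axis built without it, was at 0.278 ± 0.215 (n = 4) and medullary epithelium at 0.930 ± 0.212 (n = 3). Thymoma lay below medulla (exact two-sided permutation test, p = 0.0286, the smallest of 35 splits) and no difference from cortex was found (exact p = 0.514). Control mice with medulla were scored on other axes than the thymoma mice, so these p-values are nominal. The test exchanged mice singly. Keeping the pairs on a slide together would leave too few arrangements for such a p. Simulated thymoma libraries placed at 0 scored 0.365 on this scale, and simulated control cortical libraries 0.185 ± 0.517, so the bias differed between classes. The place of thymoma depended on control mice. Without mouse 1172 thymoma was at 0.611, above cortex at 0.338 (exact p = 0.0286, the smallest of 35 splits), and not separated from medulla at 0.789 (exact p = 0.133 of 15 splits). Without mouse 1057 it was at −0.028, with cortex at 0.257 and medulla at 0.880 (exact p = 0.257 and 0.0667). With the mean over segments in place of summed counts it was at 0.684, with cortex at 0.463 (exact p = 0.0571) and medulla at 1.02 (exact p = 0.0286). Without mouse 1143 thymoma was at 0.052 ± 0.129, cortex at −0.060 and medulla at 0.796 (exact p = 0.0667 against medulla, the smallest that 15 splits allow).

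**Figure D3:**
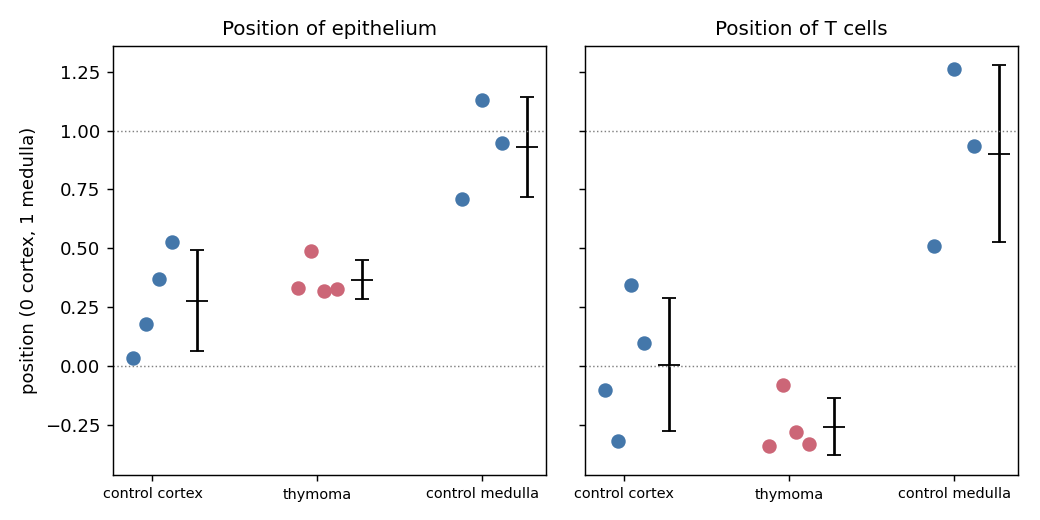
Position of each mouse between control cortex (0) and control medulla (1), for epithelium and for T cells, with the mean and SD beside the points. Thymoma epithelium averages 0.367 and thymoma T cells −0.258, below every medullary mouse in both segment types.

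Thymoma T cells were compared with cortical T cells of control mice to ask whether the T cells of the tumour depart from normal immature ones. With all mice, edgeR called 1 probe, lower in thymoma, against 4629 probes at an unadjusted p below 0.05, where 1009 are expected. DESeq2 called 1115. Set medians were 0.28 for the 523 epithelial probes and 0.40 for 1147 cortical probes from epithelium segments. They were 0.08 for 960 medullary probes and 0.35 for the 439 B cell probes, and no member was called. The 228 T cell probes had a median of 0.20 (camera adjusted p = 2.7e-05, 0.532 with an estimated correlation, fry 0.241). The 95 probes lower in B cell segments had one of 0.07. Sets of opposite kind thus rose together. Level-matched lists stood at 0.136 for the cortical set and 0.150 for the B cell set. The cortical set depended on the setting: its median was 0.63 against the Gtf2ifl/wt controls, 0.25 against the Gtf2ifl/fl controls and 0.17 under quantile normalization, which lay 0.46, 0.084 and 0.136 above level-matched lists, from 0.264. For the B cell set the camera adjusted p was 1.26e-21, the adjusted p with an estimated correlation 0.124 and the fry adjusted p 0.0139.

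That count rested on mouse 1143. Without it, 1355 probes were higher in thymoma T cells and 1679 lower. Of the epithelial probes 178 then rose and 7 fell, of the cortical 215 rose and 2 fell, of the medullary 165 rose and 20 fell, and of the B cell probes 160 rose and 6 fell. Under quantile normalization, added after the data were seen, these numbers were 88 and 0, 35 and 3, 72 and 5, and 67 and 1. The median of the cortical set went from 0.364 to 0.066, which lay 0.158 and 0.071 above level-matched lists. No other single mouse left out raised the count above 1. One other split of those 7 mice called more probes, 4130, with thymoma mouse 1082 placed among the controls, so the count of 3034 was not beyond what other splits gave.

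Against medullary T cells, probes that marked the cortex in control epithelium segments were higher in T cell segments of thymoma. Of these 1147 cortical probes, 500 rose and none fell, with a median log2 fold change of 1.01. The thymoma mice lay 0.99 to 1.27 above the unweighted mean of the medulla, in which shallow mouse 1143 weighs like the others. This range is not on the scale of the edgeR median and runs higher. The set had a camera adjusted p of 9.8e-89, which was lost with an estimated correlation (adjusted p = 0.123), and a fry adjusted p of 0.0084. Against mouse 1057, the only Gtf2ifl/fl control with medulla, the set median was 0.76 and the set less matched lists 0.576. Without mouse 1042, 1 probe in all was called higher, and without mouse 1082, 1157 or 1172 none was. Of 960 medullary probes, 94 fell and 2 rose, with a median of −0.19, and the mice lay between −0.27 and −0.11. Of 596 probes that marked epithelium in the cortex, 59 rose and 4 fell, with a median of 0.46. Without mouse 1143, 859 cortical probes rose and none fell, 183 medullary fell and 9 rose, and 130 epithelial rose and 9 fell. Against mouse 1057, set less matched lists was −0.194 for the medullary set, and 0.131 for the epithelial set, from 0.272. The cortical and medullary sets came from epithelium segments of the same control mice and regions. Part of their movement thus follows from how they were chosen.

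This comparison called 791 probes higher and 253 lower. Set less matched lists was 0.81 for the cortical set and −0.15 for the medullary set (camera adjusted p = 1e-07, adjusted p = 0.232 with an estimated correlation, fry adjusted p = 0.0333, lost without mouse 1143 at 0.0905). Position placed thymoma T cells at −0.258 ± 0.121 (n = 4), cortical T cells at 0.005 ± 0.283 (n = 4) and medullary T cells at 0.901 ± 0.376 (n = 3), with an exact permutation p of 0.171 against cortex and 0.0286 against medulla, the smallest of 35 splits. These p-values are nominal too, since the axes differed between thymoma and control mice. Simulated thymoma T cell libraries placed at 0 scored 0.123, and simulated control cortical ones 0.19 ± 0.063. Upper-quartile scaling gave 895 higher and 3168 lower with a median of −0.31 over all probes, and quantile normalization 978 and 636. The count of 1044 was 0 without mouse 1157 (4368 at an unadjusted p below 0.05), 1 without 1082, 3 without 1042, 5 without 1172, 106 without 1044 and 2985 without 1143.

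**Figure D4:**
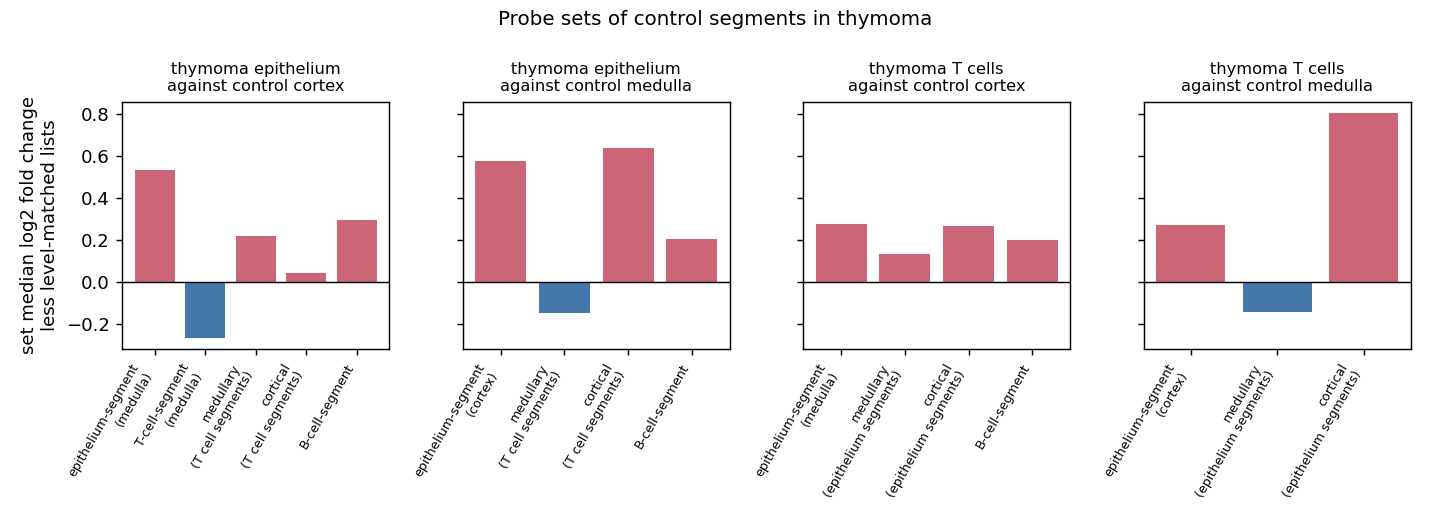
Median log2 fold change of probe sets defined by control segments, less that of lists with the same mean level, in the 4 comparisons of epithelium and T cells. The cortical sets stand at 0.64 and 0.81 against medulla, and the medullary sets at −0.15 in both.

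Between B cells of thymoma and B cells of control thymus, almost no probe was called. Of 20171 probes, 1 was called, RTS0081028, with a log2 fold change of 2.01 (SE 0.269, adjusted p = 0.00469), the probe that was also higher in thymoma epithelium. At an unadjusted p below 0.05 there were 1832, where 1009 are expected, and DESeq2 called 14. None of the 1039 cortical, 951 medullary and 596 epithelial probes of the cortex was called, with medians of 0.03, 0.04 and 0.02. Nor was any of 21 probes that marked T cell segments in control cortex, with a median of −0.14. Their camera adjusted p was 0.0438 at the preset correlation and 0.232 at an estimated one, and the fry adjusted p 0.0514. Of 2863 probes that marked epithelium segments in thymoma 1 rose, and of 2227 that marked T cell segments there none was called, with medians of 0.02 and −0.03. Simulated changes of 1.5-, 2- and 4-fold in 200 of 20168 probes were recovered at 38.8%, 94% and 100% in this comparison. Small changes would thus mostly be missed. Larger ones could be missed in the real fit too. There RTS0081628 had a log2 fold change of 3.33 (edgeR adjusted p = 0.369) and RTS0067343 one of −1.03 (0.318), and neither was called. The probe lost its call without mouse 1059 or 1172. Area per nucleus under the B220 mask was 31.4 ± 3.73 square micrometres in thymoma and 47.7 ± 5.44 in control (n = 4 each, exact permutation p = 0.0286, adjusted over 15 tests 0.143).

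The last comparison asked whether thymoma shifted epithelium and T cells of the same mouse by different amounts. In one fit of both segment types with mouse as a block, 334 probes differed, 245 with a larger change in epithelium and 89 with a larger change in T cells, taken with their sign. The count was 57 without mouse 1057, 80 without 1172 and 187 without 1059, and 253 and 171 under upper-quartile scaling. The spread of the log2 difference between epithelium and T cell libraries of a mouse was 0.254 ± 0.018 in thymoma and 0.681 ± 0.889 in control cortex (n = 4 each, exact permutation p = 0.714). Without mouse 1143, which stood at 2.01, the control value was 0.238 ± 0.077 (n = 3, exact p = 0.657). These libraries differ in depth. Thinned to a common total without that mouse, a setting added later, thymoma was at 0.387 and control at 0.328 (exact permutation p = 0.0286).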

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

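In this part, the tests with thinned libraries, quantile normalization and level-matched lists, and the splits without mouse 1143, were chosen only after the results were seen. The comparison behind the epithelial and T cell sets of control medulla was not fixed in advance either.

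Between thymoma and control cortical T cells, 1 probe was called with all mice and 3034 without control mouse 1143. The spread between epithelium and T cell libraries of that mouse, 2.01, lay far from 0.165, 0.228 and 0.318 in the other control mice. With all libraries thinned to the same total it was 0.66, against 0.58 to 0.61 in those mice. Most of that distance thus went with the low total of mouse 1143. Counting noise from its low total was tested by thinning 1 other control mouse to that total, which left 2477 calls for mouse 1057, 2037 for 1059 and 121 for 1172, so depth cannot be told apart from the profile of the mouse as the reason. A profile that differs beyond counting noise stays open: the SD of its log2 difference from the other controls was at least 0.93, against at most 0.427 in other mice thinned to the same total, a ratio of 2.18. Tissue quality may lie behind such a profile, but nothing here measures it. No biological explanation was tested, since the mouse shares slide and genotype with mouse 1172.

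The probes that marked epithelium segments in control medulla rose in thymoma against cortical epithelium, 164 of 523, with 1 lower. Stronger signal over background in thymoma was tested with quantile normalization, which gives every library the same distribution. The set median still lay 0.535 above level-matched lists, and 0.434 to 0.599 with single mice left out. A wider distribution of counts as the only cause is thus argued against. The 99th percentile over the median was 14.8 in thymoma and 11.4 in cortical epithelium (exact permutation p = 0.0571, adjusted 0.143). Quantile normalization keeps the ranks of probes, and the lists were matched on level over all segments. Background that changes ranks therefore stays open. A peculiarity of 1 control slide is argued against as well, since the difference was 0.51 with the Gtf2ifl/fl mice and 0.557 with the Gtf2ifl/wt mice alone, although 75 of its probes rose and 2 fell with the former and none was called with the latter, against which edgeR called 1 probe in all (3574 at an unadjusted p below 0.05). Fewer T cells inside the epithelial masks of thymoma could account for the rise, though the values go both ways. Under the same normalization the T cell set lay −0.276 from its matched lists and the B cell set 0.353. With TMM the T cell set was at −0.134 with the Gtf2ifl/wt mice and −0.335 with the Gtf2ifl/fl mice. Its median in single thymoma mice, before matching, lay −0.077 to 0.277 from a control mean that weighs shallow mouse 1143 like the others. The edgeR median of the set was −0.09. These single values are thus on another measure and do not speak against fewer T cells. This set came from medullary segments, while the control masks compared were cortical. The 1039 probes that marked cortex in T cell segments lay 0.041 from matched lists with TMM and −0.029 under quantile normalization. A change in the tumour epithelium itself and any trait of the thymoma slides stay open, untested, because slide lies within group.

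A difference between compartments in the effect of thymoma was found for 334 probes by the test of the interaction. The highest of the other 34 splits of the mice gave 51. This excludes chance only if mice can be exchanged singly, and with slide pairs kept together the arrangements are too few. The count fell as low as 57 with a single mouse left out.

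The position of thymoma epithelium in mouse 1044, 0.491, lay far above the other 3 thymoma mice, at 0.319 to 0.330. Of 31 groups examined for a sample far from the others, 2 had one, where chance gives about 1.6.

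Every other split of the mice was counted beside the real one, 35 in all for each thymoma comparison. These splits, and those of the interaction, exchange mice singly and ignore slide; keeping the pairs on a slide together leaves 3 arrangements, too few to exclude chance. With mice exchanged singly, chance is excluded for thymoma epithelium against cortex (691 real, 0 the highest other, 1 split as large) and against medulla (2036 and 9), and for T cells against medulla (1044 and 42). It is excluded for epithelium against cortex without mouse 1143 as well (1910 and 947). For T cells against cortex the real split called 1 probe and the highest other 0, so a single probe decides. Without mouse 1042, 1044, 1057, 1059, 1157 or 1172 edgeR called 0 (2271 to 4298 at an unadjusted p below 0.05), and without 1082 it was 1 in the opposite direction, so chance is not excluded there. For B cells 3 of 35 splits called at least 1 probe and the highest other 26, with mice 1042, 1044, 1057 and 1143 together, so chance is not excluded. For T cells against cortex without mouse 1143, 2 of 35 splits gave as many as the real 3034. The other, with 4130, put thymoma mouse 1082 with controls 1057, 1059 and 1172, and the same grouping gave the 947 in epithelium. It differs from the real grouping by mouse 1082 alone, and a structure beyond the 2 groups was not tested. For comparisons within mice the 4 or 8 ways to swap classes are too few for a share under 0.05: medulla against cortex gave 2107 in epithelium (highest other 924) and 1991 in T cells (343), and epithelium against T cells 617 in control cortex (571) and 5092 in thymoma (0).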

How the results depend on the processing

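Quantile normalization, thinned totals, level-matched lists, set medians under other choices, set tests without mouse 1143 and the position with axis and scale from different mice were chosen only after the results were seen; the other settings were planned. RLE normalization, no low-count filter and leaving out segments with few nuclei kept each of the 10 counts of called probes within 1.5 times, and no called direction of the 4 named probes turned under any setting. Unless noted the cause was not tested.

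Upper-quartile normalization gave 1225 for thymoma epithelium against cortex, 4959 against medulla, 0 for T cells against cortex (5947 at an unadjusted p below 0.05) and 4063 against medulla. The upper part of probes by level gave 357, 978, 0 and 583, and 0 for B cells, with fewer probes tested. The DESeq2 Wald test gave 3547 for epithelium against medulla, 1115 for T cells against cortex, 2755 against medulla, 14 for B cells, 385 and 552 for medulla against cortex in epithelium and T cells, 167 for epithelium against T cells in control cortex and 2451 in thymoma. The limma test on mean log2 values per mouse gave 10 for epithelium against medulla, 6040 for epithelium against T cells in thymoma, and 0 for the other 8 comparisons, with 94 to 3937 probes at an unadjusted p below 0.05; it weighs shallow segments like deep ones. Segments with mouse as a random block in limma-voom gave 1952, 4493, 2264 and 4237 for the 4 thymoma comparisons in the order above, 25 for B cells, 694 and 1091 for medulla against cortex, 216 for epithelium against T cells in control cortex and 118 for the interaction. Quantile normalization gave 377 for epithelium against cortex, 20 and 1614 for T cells against cortex and medulla, 0 for B cells (1538 at an unadjusted p below 0.05), 620 and 1137 for medulla against cortex, 234 for epithelium against T cells in control cortex and 44 for the interaction.

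With only the Gtf2ifl/wt controls, fewer mice by construction, the counts were 1 for epithelium and 0 for T cells against cortex, 0 for B cells and 4 for the interaction. With only the Gtf2ifl/fl controls they were 197 for epithelium and 7 for T cells against cortex, 0 for B cells and 50 for the interaction. Against medulla they were 202 and 25, but that side was mouse 1057 alone, since mouse 1059 had no medulla. Without the replicate block, which the pairing within mice calls for, medulla against cortex gave 0 in epithelium and 1 in T cells, and epithelium against T cells 0 in control cortex and 13 in thymoma.

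Leaving out each mouse gave 50 to 1910 for epithelium against cortex, 30 to 3627 against medulla, 0 to 3034 for T cells against cortex, 0 to 2985 against medulla, 0 to 1 for B cells, 668 to 2408 and 547 to 2438 for medulla against cortex in epithelium and T cells, 220 to 790 for epithelium against T cells in control cortex, 3566 to 4437 in thymoma and 57 to 410 for the interaction. Positions ran from −0.028 (without 1057) to 0.611 (without 1172) in epithelium and −0.362 to −0.052 (without the same mice) in T cells. Leaving out a thymoma or medullary mouse leaves too few splits for a p below 0.05 against medulla, and without mouse 1172 the separation of epithelium was lost besides (p = 0.133 of 15 splits). The position of epithelium was 0.104 on the axis of 200 probes, 0.502 with prior count 0.5, 0.684 with the mean over segments and 0.783 on the axis of all probes, with cortex at 0.121, 0.356, 0.463 and 0.720 and p = 0.0286 against medulla each time. For T cells these were −0.157, −0.257, −0.309 and −0.086. The spread in thymoma less that in control ran from −0.577 to 0.0168, its sign turning without mouse 1143, and was 0.0589 without that mouse at thinned totals.

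Of 28 set tests, 20 passed with camera at a preset correlation, 0 with an estimated one (lowest adjusted p 0.123) and 8 with fry. Without mouse 1143, 17 passed with camera at a preset correlation, 0 with an estimated one and 4 with fry. In thymoma epithelium against cortex, the cortical set less matched lists turned from 0.041 to −0.029 under quantile normalization, where single mice left out gave −0.046 to 0.033, and to −0.049 with the Gtf2ifl/fl controls. Probe RTS0081028, above the median by its mean log2 level in the edgeR fit, lay below it by plain mean CPM and has no value under the stricter filter.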

Other observations

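In this part, the comparison of B cell with T cell segments, the overlaps between comparisons, the thinned spread, the measures of depth, quantile normalization, level-matched lists and the position with axis and scale from different mice were chosen only after the results were seen.

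B cell segments of thymoma shared many markers with those of control thymus. Within thymoma mice, 1453 probes were higher in B cell than in T cell segments and 2580 lower (edgeR, mouse as a block). Of 439 probes higher in B cell than in medullary T cell segments of control mice, 299 were also higher in thymoma, where independent lists would share 31.8, and 140 were not called higher; no mouse is in both contrasts. Of 95 lower in control, 67 were also lower, where 12.2 would be shared. The likeness was partial: over all probes, which are not independent replicates, the fold changes of both contrasts correlated with r = 0.351, and 53.5% of the 2580 lower in thymoma had the same sign in control. Whether these lists hold probes of the gating markers was not checked, for lack of gene names.

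Fold changes against control cortex were compared between epithelium and T cells. Without mouse 1143, 713 probes were higher than in control cortex in both segment types and 420 lower in both, and no probe was called in opposite directions. Across probes, which are not independent replicates, both fold changes correlated with r = 0.871, but the same mice and slides enter both, and of 35 splits of these mice 2 gave as high an r, the other 0.882, with a median of 0.706 over the splits other than the real one. Chance is not excluded for a shared direction.

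With axis and scale from different control mice, thymoma epithelium was at −0.165 ± 0.154 (n = 4), cortical epithelium at −0.182 ± 0.443 (n = 4) and medullary epithelium at 0.940 ± 0.337 (n = 3), with an exact permutation p of 0.971 against cortex and 0.0286 against medulla. With all mice simulated epithelium placed at 0 still scored 0.277 on this scale, so this value is biased. Without mouse 1143, where such libraries scored −0.007, thymoma epithelium was at 0.016 ± 0.152 and thymoma T cells at −0.095 ± 0.135.

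With all libraries thinned to the same total, the spread between epithelium and T cell libraries was 0.606 in thymoma and 0.610 in control (exact permutation p = 0.886). Without mouse 1143 and thinned to a higher total it was 0.387 ± 0.019 in thymoma (n = 4) and 0.328 ± 0.025 in control (n = 3), with an exact permutation p of 0.0286, the smallest that 35 splits allow.

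The mice are too few for a measure of depth or mask to pass adjustment easily: the smallest p was 0.0286, and its adjusted value over 15 tests 0.143. The 99th percentile of counts divided by their median was 14.8 ± 2.12 in thymoma epithelium (12.7 to 16.7, n = 4) and 8.55 ± 1.83 in medullary epithelium (6.45 to 9.75, n = 3). In T cells it was 14.6 ± 2.50 (12.3 to 17.8) and 8.98 ± 2.18 (6.58 to 10.8), with an exact permutation p of 0.0286 in both. This ratio rose together with the cortical sets, which under quantile normalization, where every library has the same distribution, still lay 0.594 above matched lists in epithelium and 0.701 in T cells. Area per nucleus was 82.1 ± 16.3 square micrometres in thymoma epithelium and 47.4 ± 19.6 in cortical epithelium (n = 4 each, exact permutation p = 0.0571, adjusted 0.143).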
